A study of Homo sapiens with 4 samples.

How the data were processed

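CLIP-seq (UV crosslinking, immunoprecipitation and sequencing of the RNA bound to a protein) was done for SAF-A in HCT116 cells. SAF-A, scaffold attachment factor A, is a nuclear RNA- and DNA-binding protein also known as hnRNP U, and HCT116 is an established human colorectal carcinoma line. Per the labels' protocols, cells were crosslinked with ultraviolet light, lysed, treated with DNase and a small amount of RNase A, and the cleared lysate was divided between input and an immunoprecipitation with a SAF-A antibody. For both kinds of sample, RNA was recovered from the membrane region at the size of SAF-A and somewhat above it, so the input is a size-matched background. There were 2 input and 2 pull-down samples. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

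The authors deposited 1 peak list per sample, so peaks were called per sample and not on pooled samples. Each row gives a chromosome, a start, an end, a score and a strand. The submitters' processing notes name STAR, featureCounts and GRCh38, with no versions. The peak caller and its threshold are not given in the sources used here. The score deposited by the authors is a whole number, at least 10 in every list, whose meaning is not stated. It was therefore used only to rank or filter peaks within a list. No peak was wider than 201 bases. The other deposited values are positions, in bases. Read depth is unknown, because the values used here are peaks and not reads. A longer list can reflect deeper sequencing as well as more bound sites.

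The positions do not match the build named in the processing notes. Of the 278492 nuclear peaks in the 4 lists, 1214 end past the GRCh38 end of their chromosome, on 15 of 24 chromosomes, and 0 end past the GRCh37 end. All positions are therefore given as in the files, 1-based, and are taken as GRCh37. The chromosome lengths of both builds were taken from general knowledge. The only gene table used here was RefSeq on GRCh38.p14, so nuclear peaks were not assigned to genes, introns or untranslated regions. The planned comparisons of region classes, biotypes, nuclear gene lists, 5-mers and positions within introns were not run. The exception is the mitochondrial genome, whose sequence is taken to be the same in both builds. Its peaks were assigned by midpoint to the 37 mitochondrial genes of the table, on either strand. Moving every mitochondrial peak by 2 bases to either side changed 0 of 446 assignments.

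Peaks were compared by overlap of at least 1 base on the same strand. Chance overlap was estimated from 100 draws in which each peak was moved by a random 1 to 10 kb. This replaced the planned placement inside the same genes. Peaks found in both pull-downs were merged, and those overlapping a peak of either input were removed. Shares per library carry 95% Wilson intervals, which cover counting error only, since neighbouring peaks are not independent. Group values are means ± SD over 2 samples. With 2 samples against 2, the two-sided exact permutation test cannot give a p below 0.333, so no comparison of single values can reach 0.05 in that test.

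For a test across the genome, peaks were counted in 1 Mb regions, on both strands together, and divided by the length of the list. Values were log2 of peaks per 10000 listed peaks, with 0.5 added to each count. Regions with a mean of at least 10 peaks were tested in limma (lmFit and eBayes with a mean trend) with Benjamini-Hochberg adjustment at 0.05. This test and the comparisons of peak width and of strand were added after the files had been examined. On simulated lists for this comparison, with 2721 regions tested and each site listed with the chance at which replicates shared peaks, the test recovered 78.8% of the 85 regions changed 2-fold that passed the minimum and 39.4% of the 94 changed 1.5-fold that did, out of 100 changed for each fold, with 0 false calls. Beyond list length, simulated replicates differed only by which fixed sites were listed. The recovery and the 0 false calls hold for that setting and may not hold for the real lists.

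The rules for named items were set before the data were examined. With no nuclear gene names, the rule for the 12 genes with the most reproducible input-free pull-down peaks was applied to 100 kb windows on 1 strand. The rule for the 5 genes with the most input peaks found in both inputs and no pull-down peak was applied to the same windows, with ties broken by position. Fewer than 5 mitochondrial genes met it, so there the fixed fallback named the 5 genes with the lowest pull-down to input ratio among those with at least 5 input peaks. Of each gene list, up to 4 members with the most reproducible input-free pull-down sites were to be named. All 13 mitochondrially encoded protein genes had 0 such sites, so ties were broken by symbol, which named ATP6, ATP8, COX1 and COX2. The rule for the 8 genes with the most peaks per kb, those for HNRNPU and other single genes, and all gene lists but the mitochondrial one could not be applied. The 5 regions with the largest ratio in each direction, among called regions with a peak in all 4 libraries, were added to these rules. Narrow peaks are at most 20 bases wide and wide peaks at least 50 bases. The alternatives were a reciprocal overlap of 50%, ignoring strand, the better-scoring 50% of each list, lists shortened to the length of the shortest, leaving out each replicate, a replicate block, and other region sizes and minimums. Those that kept narrow or wide peaks alone or removed pull-down peaks with an input peak, and all of those for the overlap of pull-down with input lists, 1 Mb regions, strand and the share of wide peaks, were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. Overlap and merging were tested on simulated data.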

Results

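The RNA contacts of SAF-A, a nuclear scaffold protein that binds RNA, were profiled in HCT116 colorectal carcinoma cells by CLIP-seq. The design set 2 pull-down samples against 2 size-matched input samples. The peak lists of the inputs held 29386 and 42256 peaks (replicates 1 and 2), and those of the pull-downs 96061 and 111256. Peaks had a median width of 14 and 16 bases in the inputs and of 15 bases in each pull-down. They lay evenly on both strands, with 49.7% to 50.5% on the plus strand in all 4 libraries.

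The first comparison asked how many sites each kind of library listed. Pull-down lists held 2.89 times as many peaks as input lists, with 103658 ± 10744 against 35821 ± 9100 (SD, n = 2 each). They covered 3316 ± 555 kb against 1406 ± 463 kb (SD, n = 2 each). Wide peaks, of at least 50 bases, made up a smaller part of the pull-down lists. Their share was 17.7% ± 2.1 in the pull-downs and 24.3% ± 3.1 in the inputs (SD, n = 2 each). Both pull-downs lay on the same side of both inputs in all 3 measures, for which the two-sided exact permutation p was 0.333, the smallest that this test allows with 2 against 2 samples. In lists of equal length the difference in the share of wide peaks was -12.96 percentage points against -6.60, and without input replicate 2 it was -4.38. Shortening kept the best scores, and wide peaks scored lower than narrow ones (medians of 14 and 20 in each pull-down). The pull-downs were cut most, so a larger difference would arise by construction and is not a separate check. Read depth is unknown, so the peak number cannot be set against the number of reads.

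The second comparison asked whether the same sites were found again. Of the peaks of pull-down replicate 1, 65.6% (95% Wilson interval 65.3 to 65.9) overlapped a peak of replicate 2, and 56.7% (56.4 to 57.0) of those of replicate 2 overlapped one of replicate 1. Between the inputs, 77.7% (77.2 to 78.2) of the shorter list and 54.1% (53.7 to 54.6) of the longer list were found again. Peaks moved by 1 to 10 kb on the same strand overlapped at a mean of 0.53% for pull-down replicate 1 in replicate 2 and of 0.66% for input replicate 1 in replicate 2. The highest of 100 draws were 0.58% and 0.76%, below the observed shares. This excess was not particular to replicates. Overlaps between pull-down and input lists were also 104 to 159 times their shifted means, against 125 times between the pull-downs. With an overlap of at least 50% of both peaks, 53.2% and 45.9% of the pull-down peaks of replicates 1 and 2 were found again.

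The third comparison set pull-down peaks against input peaks. In lists of equal length, each of the 29386 best-scoring peaks, 44.5% to 47.2% of pull-down peaks were found in an input and 44.5% to 47.3% of input peaks in a pull-down, while 56.0% of the peaks of each pull-down were found in the other and 68% and 68.1% between the inputs. The whole lists differ in length, which limits the overlap in 1 direction. Of the peaks of input replicate 1, 66.2% overlapped a peak of pull-down replicate 1 and 67.9% one of replicate 2. In the other direction, 20.3% of the peaks of pull-down replicate 1 overlapped input replicate 1 and 27.6% overlapped input replicate 2, whose lengths were 30.6% and 44.0% of that of the pull-down list. The overlap of pull-down peaks with the inputs depended on the score, and that of input peaks with the pull-downs did so less. Of input peaks scoring 10 to 14, 63.9% and 59.8% (replicates 1 and 2) had a peak in either pull-down. At a score of at least 100 it was 75.4% and 75.5%. Among peaks of pull-down replicate 1 with a score of 10 to 14, 9.5% (9.2 to 9.9) had a peak in either input, against 67.7% (66.2 to 69.1) of those with a score of at least 100. For pull-down replicate 2 these shares were 8.1% (7.8 to 8.3) and 65.0% (63.6 to 66.4). The median score of pull-down replicate 1 peaks was 44 where input replicate 1 also had a peak and 17 where it had none. Of the peaks of pull-down replicate 1, 50.5% were found in the other pull-down at a score of 10 to 14, 75.4% at 25 to 49 and 70.9% at 100 or more. For pull-down replicate 2 these shares were 35.0%, 73.0% and 68.1%. Between the inputs, scores of 10 to 14 and 25 to 49 gave 66.0% and 87.7% for replicate 1 and 26.4% and 84.6% for replicate 2. A steep rise with score thus also occurred within a group, where the longer input list was looked up in the shorter. The rise in overlap with the inputs is therefore not particular to pull-down against input.

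**Figure D1:**
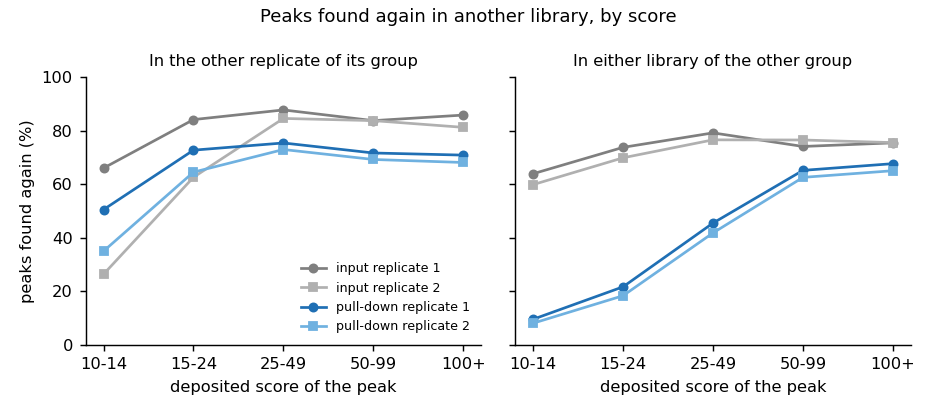
Share of peaks (percent, vertical axis) found again in the other replicate of the same group (left) or in either library of the other group (right), by the deposited score of the peak (horizontal axis), with 1 line per library. Pull-down peaks overlapped an input peak in 9.5% and 8.1% of cases at scores of 10 to 14 and in 67.7% and 65.0% at scores of 100 or more. The input lists were shorter, and shares within each group (left) were also lowest at scores of 10 to 14.

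Peaks present in both pull-downs formed 62968 merged sites, of which 35889 (57.0%) overlapped no peak of either input. These input-free sites had a median width of 16 bases, and 21.6% were wide. Both inputs shared 22803 sites, of which 4545 (19.9%) overlapped no pull-down peak. The input lists were shorter, which by itself leaves more pull-down sites without an input peak. The shares of 57.0% and 19.9% are therefore not comparable. The input sites free of pull-down peaks were of another kind. Their median width was 84 bases and 64.1% were wide, whereas input sites shared with a pull-down had a median width of 15 bases and 16.4% were wide. Chromosome 19 held 8.65% of the input sites free of pull-down peaks, 3.11% of the shared input sites and 2.19% of the input-free pull-down sites. When all lists were shortened to the 29386 best-scoring peaks, the number of input-free pull-down sites was 3577, and in the better-scoring 50% of each list it was 17400. In the shortened lists, 16465 of the 29386 peaks of pull-down replicate 1 overlapped a peak of replicate 2.

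The 5 input-free pull-down sites with the best mean rank were 25 to 93 bases wide and lay on 4 chromosomes (GRCh37). The first was a site of 35 bases on the plus strand of chromosome 7, from 82573434 to 82573468, which ranked 11 by score in replicate 1 and 4 in replicate 2. The next were a site of 25 bases on the minus strand of chromosome 12 (65192599 to 65192623) and a site of 47 bases on the minus strand of chromosome 2 (223526982 to 223527028). They were followed by a site of 28 bases on the minus strand of chromosome 11 (71362503 to 71362530) and one of 93 bases on the plus strand of chromosome 2 (217284691 to 217284783). Their mean ranks were 101.5, 119, 155.5 and 175.

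Input-free pull-down sites were spread over 24643 windows of 100 kb on 1 strand, of which 67 held at least 10 sites. The 12 windows with the most sites held 1.47% of all of them and lay in 8 stretches of 5 chromosomes. The stretch with the most sites was on the minus strand of chromosome 11 from 5300001 to 5600000. Its middle window, from 5400001 to 5500000, held 81 input-free sites. That window listed 156 and 205 peaks in the pull-downs and 25 and 47 in the inputs, or 17.3 ± 1.5 and 9.8 ± 1.8 per 10000 listed peaks (SD, n = 2 each). A window on the minus strand of chromosome 9 (21500001 to 21600000) held 65 sites, with 14.3 ± 0.5 per 10000 peaks in the pull-downs and 5.9 ± 1.7 in the inputs. A window on the plus strand of chromosome 12 (66200001 to 66300000) held 58 sites, with 13.1 ± 0.5 against 5.1 ± 1.5. On the plus strand of chromosome 2, the windows from 220500001 to 220700000 held 27 and 53 sites, and the window from 220900001 to 221000000 held 42. The first of these listed 53 and 54 peaks in the pull-downs and 1 and 3 in the inputs. The minus strand of chromosome 12 from 88900001 to 89000000 held 42 sites, and the plus strand of chromosome 10 from 114700001 to 114900000 held 28 and 36 in its 2 windows.

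The 12 windows were chosen for pull-down sites without an input peak. That choice favours a higher pull-down share in them, so the shares are no separate evidence. Even so, a high number of input-free sites did not always go with a higher share. The window on the plus strand of chromosome 11 from 65200001 to 65300000 held 31 input-free sites. It nevertheless took 10.9 ± 0.8 of every 10000 pull-down peaks against 15.2 ± 1.1 of every 10000 input peaks (SD, n = 2 each). At the other end, 217 windows held sites shared by both inputs and no pull-down peak. Those with the most such sites were on the plus strand of chromosome 1 (214800001 to 214900000), with 6 and 9 input peaks, and on the plus strand of chromosome 2 (73400001 to 73500000), with 5 and 8. The others were on the minus strand of chromosome 2 (96900001 to 97000000), with 9 and 12 input peaks, on the plus strand of chromosome 8 (145100001 to 145200000), with 5 and 9, and on the minus strand of chromosome 19 (18500001 to 18600000), with 3 and 5. The first 4 of these windows each held 5 sites shared by both inputs, and the window on chromosome 19 held 3.

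The share of peaks per chromosome asked where in the genome the pull-down lists differed from background. Chromosome 19 held 2.65% ± 0.08 of pull-down peaks and 4.71% ± 0.24 of input peaks (SD, n = 2 each), a log2 ratio of -0.83. Among the other autosomes, the lowest log2 ratios were those of chromosomes 17, 16, 22, 20 and 21, at -0.35, -0.27, -0.25, -0.18 and -0.14, and the highest were those of chromosomes 13, 4, 18 and 3, at 0.30, 0.28, 0.21 and 0.20. The sex chromosomes were counted but are not listed. Of the 25 chromosomes, the mitochondrial genome included, 10 were lower in both pull-downs than in both inputs, 13 were higher and 2 overlapped. Chance alone separates 2 against 2 samples in 33.3% of cases, and the exact permutation p was 0.333 for each separated chromosome. Chromosome 19 held 3.38% ± 0.01 of wide pull-down peaks against 8.16% ± 1.23 of wide input peaks. Among narrow peaks it held 2.31% ± 0.005 against 3.00% ± 0.21 (SD, n = 2 each).

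**Figure D2:**
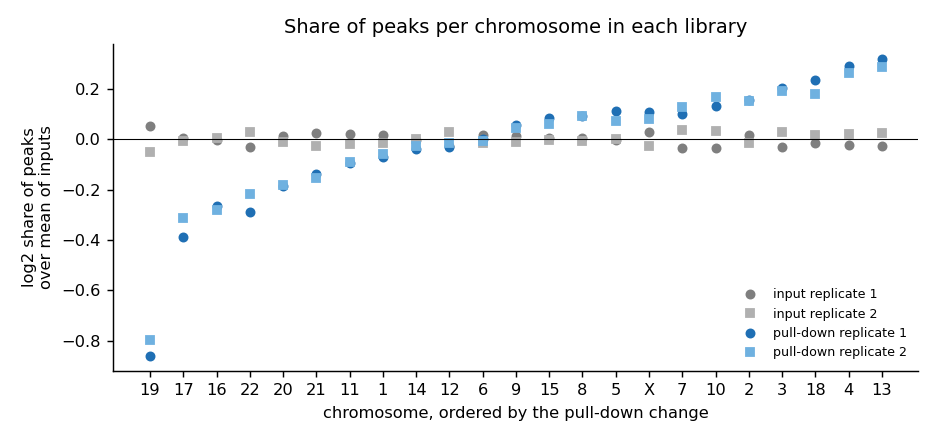
Log2 of each library's share of peaks per chromosome over the mean of the inputs (vertical axis), for the autosomes and chromosome X ordered by the pull-down change (horizontal axis), with 1 point per library. Both pull-downs lay below both inputs on chromosome 19 (mean log2 ratio -0.83) and above them on chromosomes 4 and 13 (0.28 and 0.30).

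Peaks in mitochondrial RNA, which is made and kept in an organelle outside the nucleus, were rarer in the pull-downs. The mitochondrial genome held 133 and 213 input peaks and 51 and 70 pull-down peaks. Its share was 0.453% (95% interval 0.382 to 0.536) and 0.504% (0.441 to 0.576) of the inputs, and 0.053% (0.040 to 0.070) and 0.063% (0.050 to 0.079) of the pull-downs. The mean share was 8.25 times higher in the inputs, a log2 ratio of -3.05 for pull-down over input. With 2 against 2 samples the exact permutation p was 0.333. Wide mitochondrial peaks numbered 7 and 6 in the inputs and 8 and 13 in the pull-downs, and among wide peaks alone the groups overlapped, with shares of 0.108% and 0.053% in the inputs and 0.051% and 0.061% in the pull-downs. Among them the mean log2 ratio was -0.44, and it was 0.06 without input replicate 1, so no direction is given for wide peaks. The ratio was -3.64 among narrow peaks alone and -4.03 in lists of equal length.

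The list of mitochondrially encoded protein genes, which encode subunits of the respiratory chain and of ATP synthase, had been fixed in advance. Each of its 13 members held a smaller share of peaks in both pull-downs than in both inputs, and together they took 2.87 ± 0.38 of every 10000 pull-down peaks against 30.3 ± 3.4 of every 10000 input peaks (SD, n = 2 each). Chance separates the groups in 33.3% of cases for a single gene, and the members are not independent of each other. ATP6 and ATP8, subunits of ATP synthase, had 3 and 6 and 2 and 5 input peaks, and ND4L, a subunit of complex I, had 1 and 4. These 3 genes had 0 peaks in either pull-down. COX1 and COX2, subunits of cytochrome c oxidase, had 7 and 12 and 6 and 11 peaks in the inputs, against 1 and 3 and 1 and 1 in the pull-downs. ND2, a subunit of complex I, had 6 and 9 peaks in the inputs and 1 in each pull-down. The rRNA genes were named after their values had been seen. RNR2 had 34 peaks in each input and 15 and 16 in the pull-downs, and RNR1 had 8 and 22 in the inputs and 5 and 8 in the pull-downs. Both rRNA genes together took 13.8 ± 0.7 of every 10000 input peaks and 2.12 ± 0.05 of every 10000 pull-down peaks. A site shared by both pull-downs and free of input peaks occurred 2 times on the mitochondrial genome. Numbers of 1 to 4 peaks per gene give a wide counting error. Strand was not used here, so counts may include peaks opposite to the gene. On the minus strand of the mitochondrial genome lay 44 and 66 input peaks and 21 and 31 pull-down peaks.

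Across the nuclear and mitochondrial genomes, 749 of 2776 tested regions of 1 Mb differed in their share of peaks between pull-down and input in limma at an adjusted p of 0.05. Pull-down shares were higher in 440 and lower in 309 of them. The test used 1 variance per region for both groups. Input lists were shorter, so their log2 values carry more counting error than those of the pull-downs. For regions with few input peaks the adjusted p-values may therefore be too small, and the number of higher calls too large. Chromosome 19 had 34 lower and 2 higher regions among 57 tested, and chromosome 17 had 22 lower and 10 higher among 78. Chromosome 4 had 44 higher and 6 lower regions among 183, and chromosome 13 had 24 higher and 3 lower among 90. The median region had a log2 ratio of 0.11. The minimum of 10 peaks was a mean of raw counts over the 4 libraries. Pull-down lists were longer, so it passed regions high in the pull-downs more readily than regions high in the inputs. At a minimum mean of 20 peaks, 265 regions were higher and 282 lower. When each library was centred on its median region, 308 regions were higher and 327 lower, with 1 higher and 35 lower on chromosome 19 and 28 higher and 6 lower on chromosome 4. Chromosome 13 then had 13 higher and 3 lower regions, and chromosome 17 had 6 higher and 24 lower. With pull-down replicate 1 left out 262 regions were called (89 higher), with replicate 2 left out 241 (55 higher), in lists of equal length 121 (19 higher), in the better-scoring 50% 406 (154 higher), among narrow peaks alone 47 of 2575 tested (15 higher) and among wide peaks alone 215 of 390 tested (73 higher).

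Among called regions with at least 1 peak in all 4 libraries, those with the lowest pull-down shares relative to input, in addition to the mitochondrial genome, were the last region of chromosome 19, from 59000001, the first region of chromosome 19, up to 1000000, a region of chromosome X (153000001 to 154000000) and one of chromosome 8 (145000001 to 146000000). Their log2 ratios were -3.43 (SE 0.41), -2.71 (SE 0.18), -2.36 (SE 0.17) and -2.32 (SE 0.17), with limma adjusted p-values of 7.8e-08, 5.1e-13, 1.8e-12 and 3.3e-12. The first of these rested on 17 and 14 input peaks and 2 and 7 pull-down peaks. Called regions with 0 peaks in a library were not ranked, because their fitted ratio depends on the 0.5 added to each count. Among the ranked regions, the highest pull-down share relative to input was in a region of chromosome 3 (114000001 to 115000000). It listed 144 and 180 pull-down peaks and 7 and 20 input peaks, a log2 ratio of 2.15 (SE 0.20, limma adjusted p = 5.7e-10). Regions of chromosomes 6 (78000001 to 79000000), 1 (191000001 to 192000000), 10 (83000001 to 84000000) and 12 (55000001 to 56000000) followed, with log2 ratios of 1.88, 1.85, 1.76 and 1.74. Each of these 4 regions had 1 to 4 peaks per input library, so their ratios have a wide counting error. They passed the minimum mean of 10 peaks only through their pull-down counts. After centring, the ratios of the named regions were -3.50 to -2.38 for the lower and 1.68 to 2.09 for the higher ones.

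The strand of neighbouring peaks was compared because RNA of 1 transcript lies on 1 strand. Neighbouring peaks 1 to 10 kb apart lay on the same strand in 61.1% ± 0.8 of cases in the pull-downs and in 70.4% ± 0.5 in the inputs (SD, n = 2 each, exact permutation p = 0.333). The width of the peaks went with a larger difference. Neighbouring wide peaks shared a strand in 90.0% ± 0.3 of cases in the pull-downs and 93.2% ± 0.2 in the inputs, whereas neighbouring narrow peaks did so in 59.9% ± 0.2 and 60.2% ± 0.002. Narrow neighbours less than 1 kb apart shared a strand in 71.9% ± 1.5 of cases in the pull-downs and 83.4% ± 2.1 in the inputs, a difference of -11.5 percentage points (SD, n = 2 each, exact permutation p = 0.333). The difference went the other way for neighbours of 21 to 49 bases less than 1 kb apart, at 2.59 points, and for narrow neighbours 10 to 100 kb apart, at 0.33 points. At 100 to 1000 kb it was 0.67 points for narrow neighbours, 0.49 for those of 21 to 49 bases and 0.28 for wide ones. For all peaks together it was -0.09 points at that distance. At 10 to 100 kb, narrow neighbours shared a strand in 55.0% ± 0.1 of cases in the pull-downs, near the 50% of peaks placed without regard to strand, and wide neighbours in 69.4% ± 1.9. The reproducible input-free pull-down sites shared a strand at 1 to 10 kb in 64.0% of cases. Of the narrow peaks of the inputs, 83.7% in each replicate overlapped a pull-down peak, against 37.9% and 36.3% of the wide ones.

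**Figure D3:**
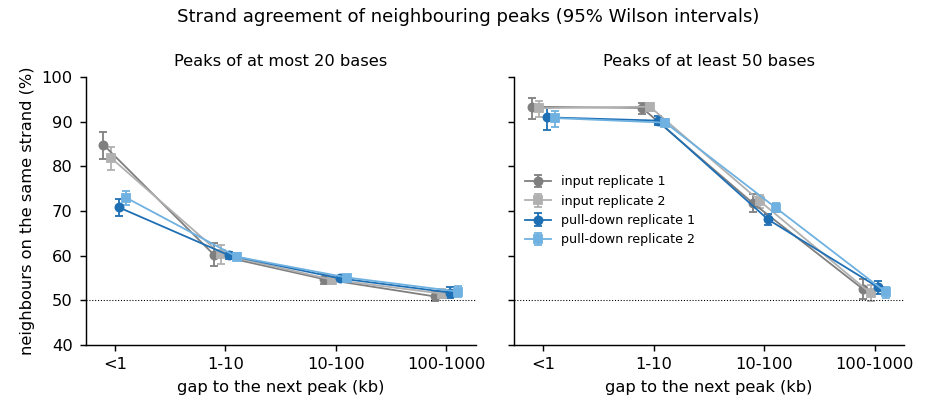
Percent of neighbouring peaks on the same strand (vertical axis, starting at 40) against the gap between them in kb (horizontal axis), for narrow peaks (left) and wide peaks (right) of each library, with 95% Wilson intervals and a dotted line at 50%. At 1 to 10 kb, narrow neighbours shared a strand in 59.9% of pull-down cases and wide neighbours in 90.0%.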

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

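Alternatives chosen after seeing the data are listed in the methods. No single-value result reversed when 1 choice was changed, but the split of called 1 Mb regions did. Of 140 values under alternatives, 91 stayed within the spread between replicates, the counting interval or 1.5 times the count, and 49 moved further. By construction, leaving out 1 library cannot move group differences beyond that spread, and a replicate block leaves them unchanged. No list held overlapping peaks, so merging them changed nothing, and keeping 50% of every list cannot change the ratio of peak numbers. These values are no checks. They are counted among the 91, so the tally does not show that most results were stable. The cause was not tested unless stated. All 70 mean values for chromosomes MT, 19, 17, 16, 22, 4 and 13 kept their sign. Leaving out 1 library or a replicate block could not change it, since the groups did not overlap. The MT value among wide peaks turned to 0.06 without input replicate 1. The log2 ratio of the mitochondrial share was -3.49 in the better-scoring 50% of peaks, -4.03 in lists of equal length, -3.64 among narrow peaks, -0.44 among wide peaks and -5.59 with input-overlapping pull-down peaks removed, which removes shared sites by construction. That of chromosome 19 was -0.38 among narrow and -1.26 among wide peaks. The wide-peak difference was -12.96 points in lists of equal length, against -6.60, where shortening favours a larger difference by construction. The strand-agreement difference, -9.28 points, was -11.05 in the better-scoring 50%, -7.76 in lists of equal length, -0.73 at 10 to 100 kb, -0.35 among narrow and -3.21 among wide peaks. A reciprocal overlap of 50% lowered the shares found again to 53.2%, 45.9%, 64.9% and 45.1% (pull-downs 1 and 2, inputs 1 and 2). The better-scoring 50% gave 63.8% and 55.1% for the pull-downs, and lists of equal length gave 56.0% for each pull-down and 68% and 68.1% for the inputs. Reproducible input-free pull-down sites numbered 17400 in the better-scoring 50%, 3577 in lists of equal length and 62968 with no removal of input, the last by construction. Mitochondrial genes with a peak in both pull-downs numbered 16, and 5 at a minimum of 3 peaks, 8 in the better-scoring 50% and 3 in lists of equal length.

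Called 1 Mb regions numbered 749 (440 higher), and 406 (154 higher) in the better-scoring 50%, 121 (19 higher) in lists of equal length, 47 (15 higher) among narrow and 215 (73 higher) among wide peaks, 725 (279 higher) with 500 kb regions, 547 (265 higher) at a minimum mean of 20 peaks and 635 (308 higher) after centring. Most calls were lower in each of these alternatives and without either pull-down replicate. They were mostly higher at a minimum mean of 5 peaks (454 of 764), with a replicate block (462 of 797) and without either input replicate. Without 1 library calls ranged from 241 (pull-down replicate 2) to 1091 (input replicate 2), with the lone library assumed to vary like the other group. Leaving out 1 library gave log2 ratios of 1.29 to 1.81 for peak number, 0.93 to 1.61 for covered bases, -3.17 to -2.92 for the mitochondrial share and -0.88 to -0.77 for chromosome 19. It gave differences of -8.82 to -4.38 points for wide peaks and -9.86 to -8.70 points for strand agreement.

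The replicate numbers were not shown to pair the samples (replicate differences of inputs and pull-downs correlated at r = 0.05 over 2776 regions). With a replicate block single-value differences were the same by construction (smallest sign-flip p 0.5). The planned comparisons that were not run had no alternatives. Depth limits what an absent peak shows: sites under the caller's unstated threshold are not listed.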

Other observations

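The tests on wide and narrow peaks within chromosome 19, on recurrence of narrow peaks and on opposite strands were chosen after the results had been seen. Further mitochondrial genes are given here, chosen after their values were seen. ND4, a subunit of complex I, took 4.87 ± 0.15 of every 10000 input peaks and 0.48 ± 0.09 of every 10000 pull-down peaks (SD, n = 2 each). ND5, another subunit of complex I, had 11 and 21 peaks in the inputs and 8 and 9 in the pull-downs, or 4.36 ± 0.87 and 0.82 ± 0.02 per 10000. CYTB, the cytochrome b of complex III, had 10 and 13 peaks in the inputs and 2 and 3 in the pull-downs, and COX3 had 9 and 15 against 2 and 4. The 22 tRNA genes together held 4 and 7 peaks in the inputs and 4 and 9 in the pull-downs, or 1.51 ± 0.21 and 0.61 ± 0.28 per 10000.

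The build of the positions was a further observation. The processing notes name GRCh38, while 1214 peaks lie past the GRCh38 ends of 15 chromosomes and 0 past the GRCh37 ends. Genes assigned to these positions through a GRCh38 annotation would be displaced.

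Chromosome 19 held a smaller share of pull-down than of input peaks. The difference remained without the weak peaks that longer pull-down lists add. Lists of equal length gave a log2 ratio of -0.82 (spread 0.13). Shortening by score also changed the share of wide peaks, which held more of chromosome 19 than narrow ones. List length and width were therefore not separated by that test. A smaller part of wide peaks in the pull-downs does not account for all of the difference. The ratio within wide peaks was -1.26 (spread 0.22), and within narrow peaks it was -0.38 (spread 0.10). The pull-down of SAF-A itself, which is what the design varied, stays open as an explanation and was not tested. The smaller mitochondrial share remained in lists of equal length, with a log2 ratio of -4.03 (spread 0.49). Of the mitochondrial peaks, 15.7% and 18.6% were wide in the pull-downs and 5.3% and 2.8% in the inputs. Wide peaks had a lower median score than narrow ones in every list. Shortening by score therefore favours a lower ratio, and list length and width were not separated here either. Among wide peaks alone, with 6 to 13 mitochondrial peaks per library, the groups overlapped, and the pull-down itself stays open and untested here too.

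Narrow neighbouring peaks shared a strand in 59.9% of pull-down cases at 1 to 10 kb, against 90.0% for wide ones. Random noise is argued against by recurrence, since 61.8% and 68% of the narrow peaks of a pull-down were found in the other. Loss of strand in the libraries is argued against by the 0.098% and 0.083% of narrow pull-down peaks that were overlapped on the other strand of the same library. A candidate explanation that stays open is that part of the narrow peaks are read stacks at fixed positions common to input and pull-down. In lists of equal length the share of narrow pull-down peaks found in an input (44.9%) was 0.81 of the share found in the other pull-down (55.3%). In the full lists, the rank correlation of scores over shared narrow peaks was 0.51 for pull-down with input and 0.74 between pull-downs. The ratio of these correlations, 0.69, lay between the bounds set in advance. They cover different sets of shared peaks, which also limits what their ratio shows. Sequence around the peaks and a map of repeats were not analysed here.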
